A study of Mus musculus with 3 samples.

How the data were processed

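RNA was measured in 3 libraries of 1 group, adipose stem and progenitor cells sorted from the epididymal fat of naive wild-type male mice. The tissue was digested with collagenase and live cells were sorted for the surface proteins named in the report, per the labels. Libraries were made with the SMARTer Ultra Low Input RNA Kit V4, per the labels' protocols, which amplifies full-length cDNA from few cells. The labels mention no molecular identifiers. The submitters' processing notes name CASAVA 1.8.2, STAR 2.3.0 and the mouse build mm10. The counting tool, gene annotation, filters and strandedness are not given in the sources used here.

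The deposited table holds whole-number read counts per NCBI gene ID, not normalized, with 27179 genes and no row for unassigned reads, and the 3 columns were matched to the samples by the number in their titles. Names and coordinates came from the RefSeq gene table of GRCm38.p6, the assembly of mm10, in which 25275 IDs matched. The 1904 unmatched IDs held 0.293% to 0.345% of the counts. In all, 7178 genes had 0 counts in every library. The limit a count of 0 allows was 3 counts. Without strand, reads of a gene and its antisense partner, such as Xist and Tsix or Wt1 and its antisense RNA, cannot be told apart. Genes with near-identical copies are uncertain, among them Ccl21a, Ccl19, C4b, Hspa1a and Hspa1b, Hba-a1 and Hba-a2, the Hbb genes, Ly6a and Ly6c1, Ifi27l2a, Il11ra1, the H2 genes and genes with processed pseudogenes such as Gapdh, Fth1 and those of ribosomal proteins. Rnase4 overlaps Ang.

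From the deposited counts, CPM were computed with TMM library sizes in edgeR 4.0.16 (R 4.3.3). Log2 values used a pseudocount of 0.5, so log2 differences understate those of genes near 0. A gene was called detected at 1 CPM or more in every library. The share of detected members in each of 48 gene lists was compared with that of all other genes by a two-sided Fisher's exact test, Benjamini-Hochberg adjusted over the 48 lists. Because the table holds many non-coding genes, the same test against protein-coding genes was added after the data were seen. List levels were differences of mean log2(CPM + 0.5) within a library, with an exact sign-flip permutation test over 3 libraries, whose smallest two-sided p is 0.25, so none of the 12 differences could pass 0.05.

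Genes varying between libraries were sought with edgeR's intercept-only model and trended dispersion (residual deviance against chi-square, 10 counts or more in at least 1 library). Each library was set against the other 2 with edgeR's quasi-likelihood test, which assumes that the lone library varies as the others do. Both were tested on simulated data for 13289 genes with 200 changed. The goodness-of-fit test found 58.0% of 16-fold and 9.00% of 4-fold changes at 10 to 100 CPM and 80.5% and 6.50% above 100 CPM, and the quasi-likelihood test 60.5%, 10.5%, 88.0% and 33.0%. In the same order, the goodness-of-fit test also called 41, 14, 52 and 22 unchanged genes beside 116, 18, 161 and 13 changed ones. Its calls thus held many unchanged genes. The quasi-likelihood test made 301, 36, 288 and 102 calls, summed over libraries. Of these, 121, 21, 176 and 66 were changed genes called in the library that was changed. The rest were unchanged genes or changed genes called in another library, which were not counted apart. With nothing changed, 6.98% of genes had a goodness-of-fit p under 0.05 and 6 were called, so its p was too small, and p from simulated negative binomial triplets was added as an alternative. DESeq2 1.42.0 gave alternative size factors, dispersions and a Wald test. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

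The 48 lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The text names the sort genes, Il33, Tslp and Il25, up to 4 members of each list with the highest mean CPM, members at 0 or below 1 CPM needed for a count, the 15 most abundant genes outside the mitochondrial genes and the 20 most variable genes. Any list member could be named. Some genes that this rule would name are not reported here. Alternatives were other detection thresholds, size factors, pseudocounts, CPM per kilobase of exon (GENCODE M21, lengths for 21572 genes), list medians, detected members, other filters and dispersions, and leaving out each library. Added after the data were seen were a threshold of 20 CPM, the protein-coding comparison set and the simulated p.

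Processed pseudogenes matching a transcript were counted with BLAST 2.17.0 (90% identity over 50% of the query, GENCODE M21). The first count used the longest whole transcript, because the intended trimming to the coding part did not take effect, and long untranslated ends then hid matches. A count with the coding sequence was added after that result was seen, and both are given.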

Results

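Transcripts were counted in 3 libraries of stromal cells sorted from the epididymal fat of male mice aged 12 weeks, to characterise the transcriptome of adipose progenitors. The sorted cells were alive, lacked CD45, CD31 and Ter119, surface proteins of leukocytes, endothelium and the erythroid lineage, and carried CD140a (the PDGF receptor encoded by Pdgfra), Sca1 (encoded by Ly6a) and podoplanin (encoded by Pdpn). The labels give 1 group of 3 numbered samples with no second treatment, genotype or cell type. The comparisons are therefore between genes and gene lists within each library, and between the 3 libraries. The libraries held 32813373, 25060096 and 27275888 counts. The limit that a count of 0 allows, taken as 3 counts, was 0.0945, 0.119 and 0.107 CPM (counts scaled to the size of each library), and it covers counting error only, because reads amplified by PCR are not independent molecules. The tissue came from 3 mice, but the labels do not say that each library was 1 mouse, so the spread between libraries may be technical in part.

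Levels are TMM-normalised CPM, given as mean ± SD over n = 3 libraries. Several genes of the extracellular matrix were among the 15 most abundant. Dcn, the small proteoglycan decorin, stood first at 42285 ± 5321 CPM, followed outside the mitochondrial genes by the nuclear RNA Malat1 at 33016 ± 8011, the actin-severing gelsolin gene Gsn at 15929.9 ± 2403 and the collagen gene Col3a1 at 9756 ± 2021. Mfap5, Ogn and Fn1, which encode a microfibril protein, a small proteoglycan and fibronectin, reached 7465 ± 542, 4726 ± 512 and 4603 ± 631 CPM. The other 8 of the 15 most abundant genes were Fos, B2m, Cyb5a, Fth1, Rnase4, Ccl11, S100a6 and Anxa1, between 3963 and 6574 CPM. Of 27179 genes in the table, 9515 (35.0%) were detected, that is, at 1 CPM or more in every library, and 9161 of 20983 protein-coding genes (43.7%).

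Genes of the surface proteins selected in the sort were abundant, and those of the excluded proteins were low. Ly6a stood at 3254 ± 441 CPM, Pdgfra at 1484 ± 14.5 and Pdpn at 119 ± 31.9. Positive genes were detected in 3 of 3 cases, which did not pass (Fisher's exact test, adjusted p = 0.074, or 0.0496 at 5 CPM), and 1 of 2 excluded genes (adjusted p = 1.0, Fisher's exact test). As 3 of 3 is the highest count that list allows, its size limits this test. Of the excluded markers, Pecam1 (CD31) had 1, 1 and 2 counts, and Ptprc (CD45) had 5.42, 15.8 and 7.68 CPM. The mean log2(CPM + 0.5) of the 3 positive genes exceeded that of the 2 negative genes by 8.52 ± 0.41, with the same sign in 3 of 3 libraries (exact sign-flip permutation test, two-sided, p = 0.25, the smallest p that 3 libraries allow). That difference was 6.48 with Pecam1, which was not detected, left out and 9.50 with a pseudocount of 0.1. Pdgfra exceeded its paralog Pdgfrb, at 157 ± 41.3 CPM, by 3.27 ± 0.43 on the log2 scale, again in 3 of 3 libraries. General mesenchymal surface genes were detected in 11 of 15 cases, led by Cd81 (883 ± 80.1), Cd9 (781 ± 58.2), Cd34 (703 ± 214) and the integrin gene Itgb1 (469 ± 21.6), more often than other genes of the table (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.011) but not more often than other protein-coding genes alone (adjusted p = 0.058, Fisher's exact test).

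Marker genes of other cell types were mostly undetected. No member was detected of the erythroid (10 measured), lymphocyte (15), granulocyte and mast cell (10), mature adipocyte (14) and testis and epididymis (12) lists, each less often than other genes (Fisher's exact test, adjusted p = 0.034, 0.0057, 0.034, 0.0088 and 0.025). Adiponectin (Adipoq), the lipid droplet gene Cidec, the T-cell kinase gene Lck and the neutrophil genes S100a8 and S100a9 had 0 counts in every library. The endothelial list had 2 of 15 members detected: Tek, an angiopoietin receptor gene, at 322 ± 64.9 CPM, and the VEGF receptor gene Flt1 at 5.29 ± 5.21 (2.28 without replicate 1), while Cdh5, Emcn, Esam, Cldn5 and Tie1 had 4 counts or fewer over the 3 libraries. The macrophage and monocyte list had 2 of 18, the fractalkine receptor gene Cx3cr1 at 23.2 ± 10.8 and the lipopolysaccharide co-receptor gene Cd14 at 14.4 ± 9.63, with Lyz2, C1qa, C1qb, C1qc and Tyrobp below 1 CPM in every library. The mesothelial list had 1 of 12 (Nkain4, 13.4 ± 9.61) and the skeletal muscle list 0 of 7. Against protein-coding genes alone, these 4 lists were also detected less often (Fisher's exact test, adjusted p = 0.035, 0.017, 0.033 and 0.039), though not against all genes. The macrophage and monocyte list also passed against all genes without replicate 1 (adjusted p = 0.047) or replicate 3 (adjusted p = 0.046, Fisher's exact test), and the mesothelial list at 5 CPM (adjusted p = 0.0496, Fisher's exact test). Lymphatic endothelial (0 of 5), mural (5 of 13, led by Abcc9 and Myl9), Schwann and neural (3 of 9) and IL-33-responsive cell (2 of 14, Rora and Il2ra) lists passed neither test. The lymphatic endothelial and skeletal muscle lists were too short to pass against all genes: 0 detected gave unadjusted p = 0.17 and 0.10 (Fisher's exact test). Against protein-coding genes the lymphatic endothelial list gave an unadjusted p of 0.073 (Fisher's exact test). At 5 CPM the erythroid and the granulocyte and mast cell calls ended (both adjusted p = 0.10, Fisher's exact test), with 0 members of either detected. Without replicate 1 the testis and epididymis call ended (1 detected, adjusted p = 0.10, Fisher's exact test). At 20 CPM, where 4735 genes were detected, 0 lists were detected less often. The 5 lists named first still had 0 members detected there (lymphocyte list, adjusted p = 0.17, Fisher's exact test). Fewer other genes reach a higher threshold, so 0 detected in a list of this size no longer passed. Calls lost in this way say nothing on other cell types.

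**Figure D1:**
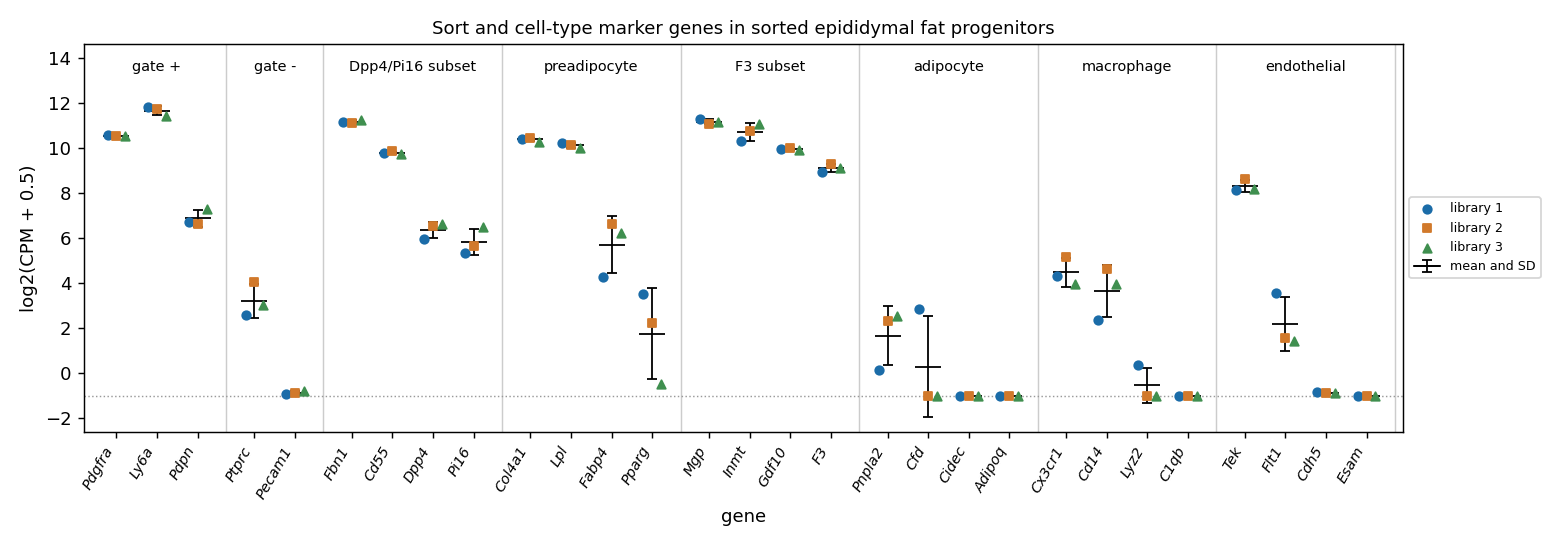
Each point is the log2(CPM + 0.5) of a gene (x axis) in 1 of the 3 libraries, the black bar and whiskers are the mean and SD, and the dotted line marks 0 counts. Pdgfra and Ly6a lie far above Ptprc and Pecam1, and Tek stands at 322 CPM beside other endothelial genes near 0.

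Most genes of 3 described subsets of adipose stroma were detected. Each library pools the sorted cells. Detection of a list therefore cannot show whether a subset was present, its share, or whether the same cells carried its genes. In the Dpp4- and Pi16-marked interstitial progenitor list, 15 of 17 genes were detected (Fisher's exact test, adjusted p = 7.1e-05), with the fibrillin gene Fbn1 at 2305 ± 122 CPM, Cd55 at 881 ± 33.1, Ly6c1 at 827 ± 73.97 and Ugdh at 772 ± 186. Dpp4 and Pi16 themselves stood at 83.4 ± 18.8 and 59.5 ± 25.4. The list of the F3-marked subset was detected in full, 12 of 12 (Fisher's exact test, adjusted p = 4.0e-05), led by Mgp (2308 ± 154), Inmt (1712 ± 440.2), Gdf10 (979.9 ± 29.5) and F3 (553 ± 75.4), the tissue factor gene. The committed preadipocyte list had 11 of 14 (Fisher's exact test, adjusted p = 0.0035), led by Col4a1 (1327 ± 71.3), the lipoprotein lipase gene Lpl (1115 ± 85.3), Sparcl1 (749 ± 7.89) and Col4a2 (554 ± 61.7). Its undetected members were Pparg at 10.7, 4.16 and 0.214 CPM, Cd36 at 15.2, 0.0793 and 0 CPM and Dlk1 with 1 count in all. The list of fibro-inflammatory progenitor genes had 11 of 13 (Fisher's exact test, adjusted p = 0.0013), led by Fn1, Ccl2, Thbs1 and Ly6c1. It shares Ly6c1 with the interstitial list.

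The order of these subset lists by level held up only in part, and in pooled cells it does not measure the shares of the subsets. By list means, the interstitial list exceeded the committed list by 0.50 ± 0.33 on the log2 scale and differed from the F3 list by -0.93 ± 0.21, and the committed minus F3 difference was -1.43 ± 0.49, each with 1 sign in 3 of 3 libraries (exact sign-flip permutation test, p = 0.25, the smallest possible). The first difference turned to -0.19 with list medians and -0.21 over detected members, and the committed minus F3 difference turned to 0.04 over detected members. The interstitial minus F3 difference kept its sign under the alternatives run, though it moved to -1.67 per kilobase of exon and -0.16 over detected members. The committed list exceeded the mature adipocyte list by 5.99 ± 0.04, and the alternatives run gave 4.47 to 7.22. With no mature member detected, this difference could not be taken over detected members.

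Most regulators of fat cell formation were detected, and 0 of 14 mature adipocyte genes reached 1 CPM in every library. The mature list was not absent: its median gene had 0.552 CPM, at percentile 60.4 of random lists from the whole table (35.5 per kilobase of exon), and 1 member was detected at 0.5 CPM or without replicate 1 or 3 (still less often, adjusted p = 0.044, 0.045 and 0.044, Fisher's exact test). Of the transcription factors that drive adipogenesis, 14 of 16 were detected (Fisher's exact test, adjusted p = 0.00015), with Klf4 at 871 ± 141, Cebpd at 440.5 ± 98.3, the glucocorticoid receptor gene Nr3c1 at 355 ± 78.7 and Ebf2 at 139.7 ± 23.2 CPM. Pparg, the central one, and Klf5 (1.54, 0.0396 and 1.21) were not detected in every library. Of the genes that restrain adipogenesis, 7 of 12 were detected (Fisher's exact test, adjusted p = 0.18, or 0.026 at 20 CPM), led by Klf2 (1173 ± 181), Wnt5a (316 ± 38.01), Foxo1 (166 ± 43.7) and Nr2f2 (134 ± 38.4), while Gata2 had 0 counts. Klf4 and Klf2, which lead these lists, are also members of the immediate-early and stress list, whose genes are induced within minutes of handling or signalling. The difference between these 2 lists, 1.19 ± 0.13 by means, turned to -0.57 by medians and -1.47 over detected members, so it gave no stable direction. The thermogenic list had 3 of 13 (Tmem26 at 8.51 ± 7.97, or 3.94 without replicate 1, Cox7a1 at 6.05 ± 3.48 and Prdm16 at 4.39 ± 3.63, or 2.40 without replicate 2), with Cidea and Dio2 at 0 counts and Ucp1 at 2 (Fisher's exact test, adjusted p = 0.64, or 0.0496 with 0 detected at 5 CPM).

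Most patterning genes of visceral fat were detected and most of those of subcutaneous fat were not. The visceral patterning list had 7 of 9 (Fisher's exact test, adjusted p = 0.025, or 0.074 against protein-coding genes and 0.12 at 20 CPM), with the mesothelial-lineage regulator gene Wt1 at 198 ± 38.1 CPM, Tcf21 at 135 ± 13.7, Gata6 at 112 ± 47.6 and Osr1 at 73.3 ± 23.7. Gata4 had 3 counts and Bnc1 had 0. The subcutaneous list had 1 of 8 (adjusted p = 0.33, Fisher's exact test), the secreted Wnt modulator gene Sfrp2 at 44.6 ± 11.8, with En1 at 0 counts and Tbx15 and Shox2 below 1 CPM in every library. The visceral list exceeded the subcutaneous list by 3.77 ± 0.57 on the log2 scale in 3 of 3 libraries (exact sign-flip permutation test, p = 0.25). Over detected members alone it was 0.12, since Sfrp2 is then the only subcutaneous gene left.

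Among genes of alarmins, cytokines released by stressed tissue cells, Il33 had the highest measured level in CPM. That rank is not corrected for transcript length, and Il33 was not compared with Il18 per kilobase of exon. Il33 (gene 77125, chromosome 19, 29925113 to 29960718, GRCm38) stood at 88.1, 130.2 and 92.7 CPM, 104 ± 23.1 on average, and Il18 at 47.2 ± 16.8. Hmgb1 was at 18.6 ± 8.51, but 113 processed pseudogenes match its coding sequence, so its level and its rank against Il33 are uncertain. Tslp (gene 53603, chromosome 18, 32815383 to 32819799) stood at 17.8, 8.6 and 28 CPM. Il25, the third epithelial-type activator of type 2 immunity, had 0 counts in every library. Set against 3 counts over the group, mean Il33 was 2937-fold higher. That ratio covers counting error only and leaves out amplification, the spread between libraries and transcript length, so it is not a lower bound. Il1a had 2 counts in all against 8679 for Il33, a ratio of 4339.5 (95% exact counting interval 1201 to 35838, which leaves out amplification and the spread between libraries), and Il1b had 3 counts. Il33 exceeded Tslp by 2.61 ± 1.11 on the log2 scale, or 1.49 per kilobase of exon, in 3 of 3 libraries (exact sign-flip permutation test, p = 0.25, the smallest possible). The list as a whole had 4 of 7 members detected (Fisher's exact test, adjusted p = 0.31).

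Of 25 chemokine genes, 19 had counts, and Ccl11, Ccl2 and Ccl7 had the highest levels. These are levels after collagenase digestion and sorting. No undigested tissue was measured, so they cannot be read as levels at rest. Ccl11, the eosinophil attractant eotaxin, stood at 4005 ± 843 CPM, the monocyte attractants Ccl2 and Ccl7 at 1399.7 ± 142 and 1366 ± 369, and Cxcl12 at 420.1 ± 81.9. Cxcl1 reached 300.3 ± 114, the B-cell attractant Cxcl13 80.4 ± 25.05, and Ccl19 8.82 ± 1.64. Ccl3, Ccl5, Ccl17, Ccl20, Cxcl5 and Ccl21a had 0 counts in every library, but Ccl21a has near-identical copies, so its reads could have been left out in counting. In all, 10 of 25 were detected, close to the share of other genes (Fisher's exact test, adjusted p = 0.74).

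Growth factors for immune cells, also measured only after digestion and sorting, were led by the macrophage factor gene Csf1 at 231 ± 66.4 CPM and Il6 at 40.8 ± 18.2. Kitl (89.9, 5.11 and 10.8) and the dendritic cell factor gene Flt3l (33.8 ± 5.37) followed, then the B-cell factor gene Tnfsf13b (24.95 ± 7.34) and Il7 (24.4 ± 4.86), the lymphocyte survival factor. Csf3 had 0 counts and Gdnf 1. In this list 11 of 19 were detected (Fisher's exact test, adjusted p = 0.083). The call came past the threshold without replicate 1 (14 detected, adjusted p = 0.0040, Fisher's exact test) and without replicate 3 (12 detected, adjusted p = 0.0499, Fisher's exact test). Of genes typical of lymphoid stroma, 8 of 15 were detected (Fisher's exact test, adjusted p = 0.22), led by Tnfrsf1a (157 ± 43.5), Vcam1 (112 ± 33), Cxcl13 and Icam1 (47.9 ± 22.7), with Madcam1 and Cr2 at 3 counts each.

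**Figure D2:**
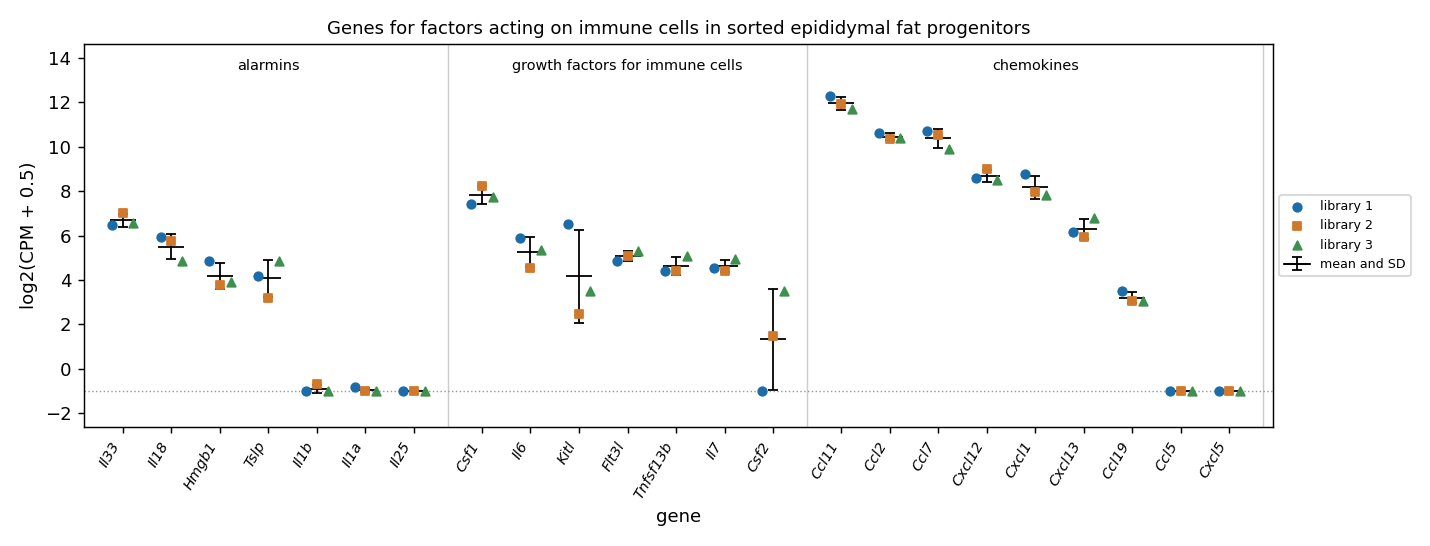
Each point is the log2(CPM + 0.5) of a gene (x axis) in 1 of the 3 libraries, with mean and SD in black and 0 counts at the dotted line. Il33 lies above Tslp in every library, Il25 is at 0, and Ccl11 is the highest chemokine gene at 4005 CPM.

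Matrix genes were detected almost throughout. Of the non-collagen matrix list, 29 of 30 were detected (Fisher's exact test, adjusted p = 5.6e-11), led by Dcn, Mfap5, Ogn and Fn1, and only tenascin C (Tnc, 7.403, 0.119 and 1.75) fell below 1 CPM in a library. Of the collagens, 17 of 22 were detected (adjusted p = 0.00034, Fisher's exact test), led by Col3a1, Col6a3 (1350.0 ± 83.8), Col4a1 and Col14a1 (1167 ± 204). The cartilage collagen genes Col9a1 and Col10a1 had 0 counts, and Col2a1 and Col11a1 had 5 and 2. Of the matrix remodelling genes, 17 of 20 were detected (adjusted p = 5.8e-05, Fisher's exact test), with the protease inhibitor genes Timp2 (2165 ± 237) and Timp3 (1534 ± 310.3), Adamts5 (1083 ± 87.9) and Adamts1 (711 ± 179.8) highest and Mmp13 at 0 counts.

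Most genes of the complement, interferon-response and MHC class I lists were detected, and most of MHC class II were not. The complement list had 11 of 13 (Fisher's exact test, adjusted p = 0.0013), with C3 at 3767 ± 699 CPM, C1s1 at 2361 ± 145 and the C1 inhibitor gene Serping1 at 2289 ± 154. Adipsin (Cfd), an adipocyte product, was at 6.77, 0 and 0. Interferon-response genes had 11 of 14 (adjusted p = 0.0035, or 0.054 at 20 CPM, Fisher's exact test), among them Ifi27l2a (1529.5 ± 99.2), Gbp2 (77.3 ± 15.6) and Irf1 (54.9 ± 14.2). MHC class I genes had 8 of 9 (adjusted p = 0.0042, Fisher's exact test), with B2m at 5714 ± 960.4, H2-K1 at 735 ± 53.7, Tapbp at 195 ± 34.3 and H2-D1 at 81.3 ± 2.22, and MHC class II genes 1 of 6, H2-Eb1 at 10.3 ± 6.45 (6.81 without replicate 2). The class I list exceeded the class II list by 5.34 ± 0.67 on the log2 scale in 3 of 3 libraries (exact sign-flip permutation test, p = 0.25), and by 3.49 over detected members.

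Immediate-early and stress genes, which are induced within minutes of handling or signalling, were detected in 23 of 25 cases (Fisher's exact test, adjusted p = 1.0e-07). Fos stood at 6574 ± 557 CPM, the heat-shock gene Hspa1b at 3461 ± 1061, Egr1 at 2953 ± 199.7 and Klf2 at 1173 ± 181. Hspa1a, nearly identical to Hspa1b, was at 1033 ± 381, and the division of reads between them is uncertain. Cell-cycle genes had 2 of 17 detected, Pcna at 55.98 ± 15.2 and Tyms at 10.5 ± 6.997, less often than protein-coding genes (Fisher's exact test, adjusted p = 0.017) though not than all genes (0.074). Aurkb and Birc5 had 0 counts.

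Signalling lists were mostly detected. The TGF-beta and BMP list had 16 of 21 (adjusted p = 0.0011, Fisher's exact test), led by Fstl1 (3017 ± 355), Gdf10, Tgfbr2 (969.6 ± 49.4) and Tgfbr3 (868 ± 157). The retinoid list had 12 of 14 (adjusted p = 0.00068, Fisher's exact test), among them Aldh1a2 (244 ± 46.8), which makes retinoic acid, Cyp26b1 (83.9, 114 and 471), which degrades it, and Dhrs3 (202 ± 102). Cytokine receptors had 19 of 22 (adjusted p = 1.6e-05, Fisher's exact test), led by Lifr (314 ± 82.3), Ifngr1 (298 ± 63.02), Il6st (269.7 ± 2.34) and Tnfrsf1a. The Wnt list had 14 of 23 (led by Wnt5a, Sfrp1, Lrp6 and Sfrp4) and the growth factor list 13 of 19 (led by Igf1, Fgfr1, Vegfa and Igf1r). Both passed against all genes (Fisher's exact test, adjusted p = 0.030 and 0.0088) and neither against protein-coding genes (adjusted p = 0.20 and 0.058, Fisher's exact test), and the growth factor call also ended at 5 CPM (adjusted p = 0.066, Fisher's exact test). Hedgehog (4 of 11) and hormone receptor (10 of 20) genes passed neither. Gli3 (119 ± 32.1) and Nr3c1 led them, and the beta-adrenergic receptor genes Adrb1 and Adrb3 had 2 and 3 counts.

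Genes that check the labels went with male mice. Y-linked genes were detected in 4 of 4 cases (Fisher's exact test, adjusted p = 0.030, or 0.058 against protein-coding genes and 0.10 at 5 CPM), with Ddx3y at 243 ± 91.6 CPM, while Xist had 10 counts in all and the list of it and its antisense RNA Tsix had 0 of 2 detected. The 10 housekeeping genes were all detected (Fisher's exact test, adjusted p = 0.00017), but Gapdh stood at 2.44 ± 0.612 and Pgk1 at 7.17 ± 2.35 CPM against 1553 ± 322 for Actb and 891 ± 23.5 for Eef1a1. Gapdh has many processed pseudogenes, so its level is uncertain. Over the 48 lists, 21 were detected more often and 5 less often than other genes, and 16 and 10 with protein-coding genes as the comparison set, which included 16 of the 21 and all 5. Genes are not independent replicates, so these tests describe these libraries.

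The 3 libraries differed most in weakly expressed genes. Over the 9515 detected genes, Pearson's r of log2(CPM + 0.5) was 0.878, 0.872 and 0.867 for the 3 pairs and Spearman's rho 0.870, 0.861 and 0.858, across genes. In each pair, 24.6% to 26.1% of genes lay more than 2-fold apart. The median coefficient of variation between libraries fell from 87.3% at 1 to 10 CPM to 36.1% at 10 to 100, 18.6% at 100 to 1000 and 12.0% above 1000 CPM. The counts of each pair differed far beyond sampling noise (chi-square per degree of freedom 153 to 194), so no count column repeats another, though separate preparations of the same cells would differ in this way too.

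**Figure D3:**
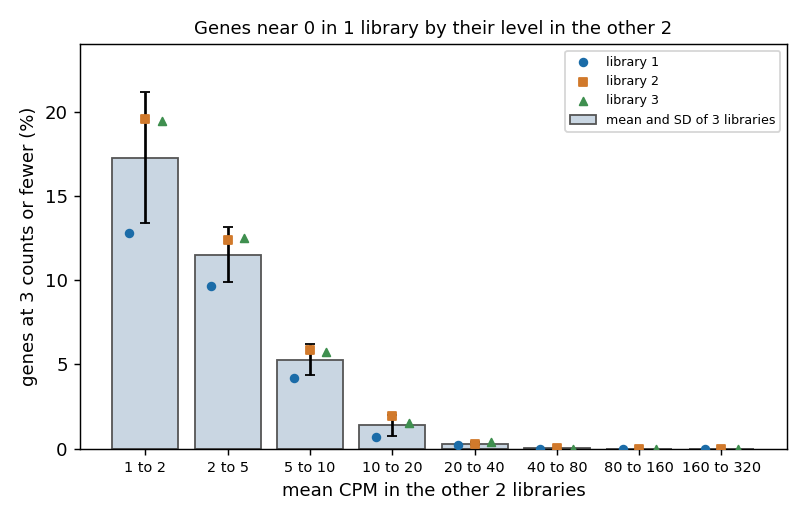
Bars give the mean and SD over 3 libraries of the percentage of genes at 3 counts or fewer in 1 library (y axis), by the mean CPM of the gene in the other 2 libraries (x axis), with each library as a point. Genes far below the bin in 1 of the other 2 libraries were left out. The percentage falls from 17.3 at 1 to 2 CPM to 0.283 at 20 to 40 CPM.

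In a goodness-of-fit test with edgeR's trended dispersion, 61 of 13289 genes varied between the libraries by more than genes of their abundance (adjusted p under 0.05), and 45 of these had a library under 1 CPM. Lin54 stood at 0.126, 79.3 and 38.8 CPM (edgeR, adjusted p = 7.9e-07), Pvt1 at 34.4, 38.8 and 0 (edgeR, adjusted p = 3.5e-05) and Noct at 56.6, 0.119 and 38.4 (edgeR, adjusted p = 3.8e-05). In 4 of the 61, 2 libraries were tied at 0, and among the others the library with the lowest value was replicate 1 for 14 genes, replicate 2 for 18 and replicate 3 for 25. The 61 held 5 genes of the fixed lists: Wnt9a (0.0315, 51.9 and 18.2), Cyp26b1, Klrg1 (0.0315, 27.5 and 0), Pdgfc (25.9, 55.04 and 0.75) and Kitl. Others among the 20 smallest adjusted p were Zfp119b, Zfp229, Tex30, Plcxd2, Gpr34, Bcap29, Efcab7, Cpe, Gtf2e1, Snrnp25, Prkar2b, Copg2, Zhx3 and AW551984. The count was 12 among genes at 1 CPM in every library and 28, 35 and 26 without replicates 1, 2 and 3. With p from simulated triplets it was 50, of which 47 were among the 61, an alternative added because the test called 6 of 13289 genes in simulated data with no change. In simulations with 200 changed genes, the test also called 14 to 52 unchanged genes, so part of the 61 may be false calls. Setting replicate 1, 2 or 3 against the other 2, edgeR's quasi-likelihood test called 0 genes for each (510, 639 and 667 at an unadjusted p under 0.05), or 16, 16 and 36 with no filter, and DESeq2's Wald test called 128, 197 and 211.

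The spread between libraries of list means over detected members was set against that of random lists. Of 26 lists with 5 or more detected members, 3 had a spread of the list mean at or above the 95th percentile of 10000 random lists matched on expression, where chance gives 1.3, with no adjustment over the lists. These were immune growth factors (percentile 98.8), fibro-inflammatory genes (97.0) and complement (96.7). On the log2 scale their SD was 0.477, 0.258 and 0.251 over detected members but 0.0992, 0.308 and 0.271 over all members, so the spread of the first depends on leaving out its undetected genes. The non-collagen matrix list had the lowest percentile of the 26 (0.070, SD 0.0022 over 29 detected members and 0.0625 over all 30, where the transcription factors of adipogenesis, at 0.0280, cytokine receptors, at 0.0299, and immediate-early and stress genes, at 0.0598, had a smaller SD).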

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

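The threshold of 20 CPM, the protein-coding comparison set and the simulated p were chosen after the data were seen. No paired analysis was possible because there is 1 group. The cause of the changes given here was not tested, except where the alternative uses fewer genes or libraries by construction. Counts of variable genes moved under 6 of 9 alternatives, counts for a library against the other 2 under 6 of 9, and differences between lists moved in 30 and turned in 5 of 87 cases. Directions turned for the interstitial minus committed difference (median over members -0.19, detected members -0.21), committed minus F3 (detected members 0.041) and adipogenic minus anti-adipogenic (median -0.57, detected members -1.47). No other difference changed sign under the alternatives run, and without 1 replicate every difference kept its sign. Committed minus mature had no value over detected members. Leaving out 1 library moved the mean of 48 of 199 named genes by over 1.5 times, 9 of them detected genes: Abcc9, Cyp26b1, Flt1, H2-Eb1, Kitl, Prdm16, Rarb, Stra6 and Tmem26. Read depth sets a floor of 0.0945 to 0.119 CPM, but at 1 to 20 CPM in the other 2 libraries 1.38% to 17.3% of genes had 3 counts or fewer, so calls on such genes are less firm. These percentages leave out genes that were far below that level in 1 of the other 2 libraries.

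Gate-positive minus gate-negative was 9.50 and 8.01 with pseudocounts of 0.1 and 1, 9.37 by medians and 6.48 over detected members. Per kilobase of exon, interstitial minus committed was 0.15, interstitial minus F3 -1.67, committed minus mature 4.47, visceral minus subcutaneous 2.83, adipogenic minus anti-adipogenic 0.54, MHC class I minus class II 4.40, Il33 minus Tslp 1.49, Il33 minus Il25 6.17, Il33 minus Il1a 6.14 and Pdgfra minus Pdgfrb 2.39. With a pseudocount of 0.1, committed minus mature was 7.16, visceral minus subcutaneous 4.65, adipogenic minus anti-adipogenic 1.77, class I minus class II 6.31, Il33 minus Il25 9.997 and Il33 minus Il1a 9.76. With 1, committed minus mature was 5.42, adipogenic minus anti-adipogenic 0.92, Il33 minus Il25 6.69 and Il33 minus Il1a 6.66. By medians, committed minus F3 was -0.91, committed minus mature 7.22 and visceral minus subcutaneous 4.91. Over detected members, interstitial minus F3 was -0.16, visceral minus subcutaneous 0.12 and class I minus class II 3.49.

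Detected genes numbered 4735 at 20 CPM, where 0 lists were detected less often, because with fewer genes detected a list at 0 no longer passed. Against protein-coding genes at 1 CPM, 10 lists were detected less often. Mean Pearson's r was 0.925 over all genes with any count and 0.879 on log2(CPM + 1), and 0.867 to 0.878 without 1 replicate. Variable genes numbered 12 at 1 CPM in every library, 811 with a common dispersion (27 shared with the 61), 106 with DESeq2's trend (all 61 shared) and 26 to 35 without 1 replicate. For replicates 1, 2 and 3 against the others, edgeR's quasi-likelihood test with no filter called 16, 16 and 36 genes and DESeq2's Wald test 128, 197 and 211.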

Other observations

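The test on Tek, the count of near-0 genes outside replicate 3 and both pseudogene tests matched by coding sequence were chosen only after the result was seen, and so was the choice of the values in the next paragraph.

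Some genes were counted mainly in 1 library. In replicate 3, the proliferation genes Mki67, Top2a and Ccna2 stood at 7.64, 11.5 and 5.86 CPM against 0.396 or less in the other 2 libraries, though none passed (edgeR goodness of fit, adjusted p = 0.82, 0.59 and 0.93) and only 5 of the 15 cell-cycle genes with any count were highest there, while Cdk1, Ccnb1 and Rrm2 had 2 counts or fewer over all 3. The retinoic acid-degrading enzyme gene Cyp26b1 was also highest in that library, with 83.9, 114 and 471 CPM in replicates 1, 2 and 3 (edgeR goodness of fit, adjusted p = 0.0025). The retinoic acid receptor gene Rarb (24.9, 16.5 and 78.8), Dhrs3 (118, 172 and 315) and the retinol transporter gene Stra6 (1.796, 1.66 and 8.07) were also highest there but did not pass (edgeR, adjusted p = 0.58, 0.59 and 1.00), and Rbp4 (74.5, 97.3 and 26.9) was lowest. Of 13 retinoid genes with any count, 8 were highest in replicate 3, and the spread of the list mean over its 12 detected members lay at percentile 92.8 of random lists. Of 13 genes of IL-33-responsive cells with any count, 7 were highest in replicate 2, 5 in replicate 1 and 1 in replicate 3, and of 6 MHC class II genes 3 were highest in replicate 2 and 3 in replicate 1, with no list test. Those highest in replicate 2 included Klrg1 at 27.5 CPM (edgeR, adjusted p = 0.0027), Siglecf (0, 8.12 and 0), Il1rl1 (0.126, 8.72 and 2.39) and Cd74 (0.756, 24.1 and 0.214), none but Klrg1 past the threshold, and Ptprc was highest there too. Macrophage and monocyte genes were highest in replicates 1, 2 and 3 in 8, 8 and 1 cases. A peak in replicate 2 was not limited to immune cell lists: complement genes had 2, 9 and 1, and TGF-beta and BMP genes 5, 12 and 4.

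The first pattern weighed is that 9 genes had 3 counts or fewer in 1 library and 20 CPM or more in both others. Sampling of reads is argued against by arithmetic alone, since 649.6 reads or more were due for each and 3 or fewer were counted, and the 0 such genes due from Poisson sampling follow from the limit of 20 CPM, so they are no separate test. A candidate explanation is that few transcript molecules were sampled before amplification, in which case the squared coefficient of variation falls in proportion to the mean. Its log2 slope on log2 mean CPM was -0.77 ± 0.01 (SE, 20 bins of 8955 genes at 5 to 300 CPM). This was below the bound of -0.75 set in advance but near it. Over 20 to 300 CPM the slope was -0.748, just above the bound. That bound was the lenient edge of the range set in advance, and both slopes were shallower than strict proportion. The SE comes from bins of genes in the same libraries, so it leaves out the spread between libraries. The slope therefore cannot decide on this explanation. A single failed or mislabelled library is argued against as the whole cause, because 4 of the 9 genes lay outside replicate 3, 2 each in replicates 1 and 2, but for the 5 in replicate 3, a share of 0.556, it cannot be told apart, because 9 genes are too few; no biological explanation was tested, since the design has 1 group.

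The second pattern is transcripts of cells that the sort removes. Whole leukocytes left in the sort, which the CD45 gate should remove, would bring their most abundant transcripts, but the median over Lyz2, C1qa, C1qb, C1qc, Tyrobp, Fcer1g and Ptprc was 0.0 CPM, and the first 6 reached at most 0.788 CPM while Ptprc stood at 9.62 ± 5.44 and Cx3cr1 at 23.2 ± 10.8. This covers macrophage-like cells, not lymphocytes or eosinophils. Endothelial cells, removed by the CD31 gate, are likewise argued against as the source of Tek at 322 ± 64.9 CPM: the median of Cdh5, Kdr, Pecam1, Emcn, Esam, Cldn5, Egfl7 and Tie1 was 0.0336 CPM and their highest value 0.25 CPM. Transcription of Tek and Cx3cr1 in the sorted cells themselves may remain as a hypothesis, and no biological explanation was tested.

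The third pattern is the low level of Gapdh and of ribosomal protein genes, which took 0.735% to 1.03% of counts. One candidate cause is that reads shared with processed pseudogenes were left out or divided in counting. Across 76 ribosomal protein genes, the number of pseudogenes matching the whole transcript and log2 CPM had Spearman's rho of -0.214 (permutation p = 0.063), between the bounds of -0.3 and -0.1 set in advance. With the coding sequence as the query, rho was -0.440 (permutation p = 9e-05, 95% interval -0.61 to -0.24, which reaches past the bound of -0.3), and 37 genes with 10 or more matches had a median of 17.8 CPM against 236 CPM for 10 genes with 2 or fewer, across genes that are not independent. Low expression in these cells cannot be told apart, because glycolysis enzymes without a matching pseudogene had medians of 34.7 CPM (8 genes, whole transcript) and 23.7 CPM (5 genes, coding sequence), against 13.2 and 29.5 CPM for those with a match, between the bounds of 10 and 50 CPM, and no biological explanation was tested.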
